A study of Homo sapiens with 2 samples.

How the data were processed

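Long-read and short-read sequencing were combined by the authors for each of the 2 samples, H1 embryonic stem cells and brain tissue of a donor with Alzheimer's disease, with 1 sample per group. Per the labels' protocols, polyadenylated RNA was made into stranded Illumina mRNA libraries and into PacBio full-length cDNA libraries, the latter after separation into 4 size fractions (bounds at 1, 2 and 3 kb). Per the submitters' processing notes, the genome build was hg38 and the tools included GSNAP and HISAT2 2.0.0, with no statement of which reads each aligned. The isoform caller, the poly(A) site caller and the annotation release are not given in the sources used here.

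Each deposited table held 1 row per isoform in 15 columns, with its gene, exons, long-read 3' ends, short-read sites and a type. The deposited values used were whole-number counts, not normalized. For each 3' end the table gave long-read counts in 3 classes, marked F, N and P, and for each short-read site counts in 2 classes, marked S and M. The sources used here do not define these letters. The deposited site column was recomputed: its long-read support equalled the class F and N reads of the isoform within 10 nt of the site in all 42006 entries of H1 and all 113947 of brain. Class P reads were in no site's support and were left out of end positions, but they count in gene totals. The type column followed the number of supported sites, with no minimum distance between them.

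Depth was 309923 long reads in H1 (272470 of class F, 20252 of N and 17201 of P) and 708910 in brain (575828, 64239 and 68843). Short-read counts at sites in genes summed to 58075 in H1 and 255012 in brain. A library with 0 reads of a gene allows up to 3 reads, or 9.68 RPM (reads scaled to the library's total) in H1 and 4.23 in brain. Exact Clopper-Pearson 95% intervals were used for shares and ratios of reads, and bootstrap 95% intervals for differences of medians by transcript length. The reads carried no molecular identifiers that the tables show, so intervals and floors cover counting error only.

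The tables named genes by Ensembl ID. Symbols came from a RefSeq gene table of assembly GRCh38.p14 by position, with an overlap over union of at least 0.5, a next-best gene at no more than 0.6 of the best, the nearer end within 500 nt, and coding genes matched to coding genes. Of 15673 genes on the autosomes and X, 12285 were named (78.4%), and of 11479 coding genes 10302 (89.7%). After displacing all genes by 1 Mb, 1.17% still found a match. Some list members are therefore unnamed here, which says nothing about their level.

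Supported sites were counted per gene as deposited and merged by single linkage. For the shift between samples, class F and N reads of the terminal exon with the most reads in both samples were grouped by single linkage within 24 nt. The mean end position was compared in genes with at least 20 such reads in each sample, and the reads at the 2 most used groups were tested with Fisher's exact test (two-sided, Benjamini-Hochberg over genes, threshold 0.05). Isoform pairs were tested the same way at 2 deposited sites over 20 nt apart. Molecule length was the exon length of the isoform up to the read's end. Gene levels were all long reads of a gene scaled to the library's long reads (RPM), mitochondrial reads included, as log2 ratios with 1 read added. Genes entered the lists with at least 50 reads in the higher sample, and a list's median was set against 10000 random lists of the same size matched on mean level in 20 bins, as a description of these libraries. Long and short reads were compared by transcript length in genes with at least 10 short-read counts and 20 long reads over both samples, with 2000 bootstrap draws. Positions are 1-based.

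The rule for named genes was fixed before the data were examined. It took up to 4 examples per gene list, by reads and by size of difference, the 10 genes with the largest shift each way past the test, the 5 genes with the most sites per sample, the 10 genes with the largest expression difference each way, and the 5 clearest isoform pairs per sample. Ties went to more reads, then to alphabetical order. Mitochondrial, unnamed and read-through genes and genes that tell sex were left out. Results for some further genes under this rule are not reported here. The 18 gene lists were fixed then too: pluripotency, neurons, astrocytes, oligodendrocytes, microglia, endothelium and pericytes, blood, cell cycle, cleavage and polyadenylation factors, regulators of site choice, genes with long 3' UTRs in brain, Alzheimer's disease, synaptic vesicles and axon transport, myelin and cholesterol, ribosomal proteins, stress, other lineages and housekeeping.

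The procedures were tested on simulated data. For the comparison of brain with H1, reads were drawn for 882 genes at their real depths, 200 of them with a changed distal share. The test called 20% of 100 genes changed by 20 points and 77% of 100 changed by 40 points, none in the wrong direction, and 1 of 682 unchanged genes. Unchanged genes had the same ends in both samples, so the calls among them do not cover a bias of library or length. Changed genes were centred on equal use of the 2 ends, and the shares called hold for that setting. The list percentile was tested with lists of 12 genes from 2366 genes: 2 of 100 unchanged lists and 84 of 100 raised by 4 on the log2 scale lay outside the middle 95%. Alternatives covered merging distances, read minimums, site and isoform filters, autosomes only, all sites of a gene, thinning of reads, scaling, the added read and the filter on low genes. Poly(A) signals were not analysed here, since no genome sequence was at hand. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.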

Results

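The study set 2 human RNA samples side by side to ask where transcripts are cleaved and polyadenylated in each, isoform by isoform. The first was H1, a human embryonic stem cell line, harvested between passages 50 and 55. The second was RNA of brain tissue from a donor with Alzheimer's disease. Each sample was sequenced as full-length cDNA on the PacBio platform (long reads) and as stranded mRNA on the Illumina platform (short reads). There was 1 sample per group, so no difference below has a replicate check, and each test on reads compares these 2 libraries, not the conditions. The deposited tables held 309923 long reads in H1 and 708910 in brain.

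H1 had 31729 isoforms of 10693 genes with an Ensembl ID, and brain had 61777 isoforms of 13830 such genes. Known Ensembl isoforms made up 54.0% of the H1 list and 35.8% of the brain list. Another 12538 spliced isoforms in H1 and 32870 in brain had no Ensembl ID, as did 2060 and 6814 single-exon loci. Many isoforms rested on 1 long read, 57.2% in H1 and 59.4% in brain. In brain 15.9% of all long reads came from *MBP*, which encodes myelin basic protein, and 19.95% from the mitochondrial genome, against 1.34% mitochondrial reads in H1. The most abundant H1 genes were *EEF1A1*, a translation elongation factor, with 1.75% of long reads, and *ACTB*, which encodes beta-actin, with 1.64%.

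The long-read molecules differed in length between the libraries. Among class F reads of nuclear genes, the largest of the deposited read classes, the median length up to the 3' end was 1879 nt in H1 and 3012 nt in brain. Molecules of 1 to 2 kb made up 49.6% of these reads in H1 and 11.1% in brain. Those of over 3 kb made up 20.6% in H1 and 50.1% in brain, and those of 6 to 7.5 kb made up 0.515% and 14.9%. Both libraries had been made from cDNA separated into 4 size fractions, with bounds at 1, 2 and 3 kb. How much of each fraction was sequenced is not given in the sources used here.

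**Figure D1:**
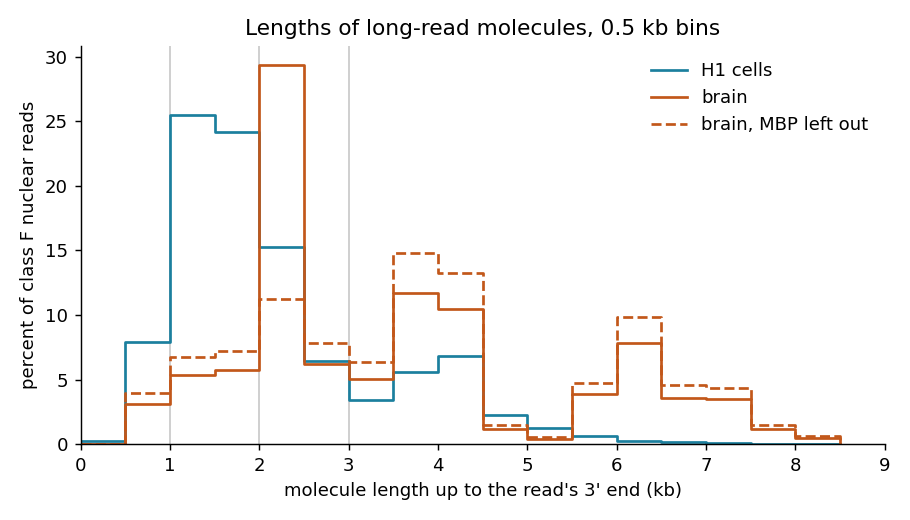
Lengths of long-read molecules (x axis, kb, in 0.5 kb bins up to 9 kb) as percent of class F nuclear reads (y axis) in H1 and in brain, with brain also drawn without *MBP*. Grey lines mark the bounds at 1, 2 and 3 kb. Molecules of 1 to 2 kb made up 49.6% of reads in H1, while 14.9% of brain reads lay between 6 and 7.5 kb, against 0.515% in H1.

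More genes had several poly(A) sites in brain than in H1 as the sites were deposited, and the difference was gone once neighbouring sites were joined. A poly(A) site counted here if the short reads placed it and at least 1 long read of the isoform ended within 10 nt. There were 11473 such sites in H1 and 24116 in brain, of which 10881 and 18974 lay on the autosomes. Of the genes with a site, 2725 of 5440 in H1 had more than 1 (50.1%, exact 95% binomial interval 48.8 to 51.4), and 4870 of 7940 in brain (61.3%, 60.3 to 62.4). With sites within 24 nt merged, the shares were 20.8% in H1 (19.8 to 21.95) and 20.5% in brain (19.6 to 21.4). Isoforms typed as alternatively polyadenylated in the deposited tables made up 47.9% of H1 isoforms with a site and 61.8% of brain isoforms with a site. In 78.3% of those H1 isoforms and 85.6% of those brain isoforms, all sites lay within 24 nt of each other, and the median gap between neighbouring sites was 3 nt in H1 and 2 nt in brain.

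**Figure D2:**
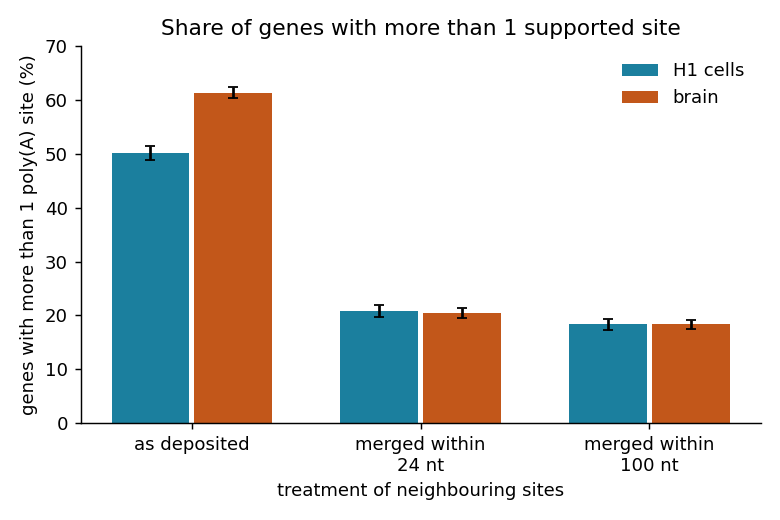
Percent of genes with a supported poly(A) site that had more than 1 (y axis), in H1 and brain, for sites as deposited and merged within 24 or 100 nt (x axis). Error bars are exact 95% binomial intervals, which cover counting error only. The bars differ as deposited (50.1% and 61.3%) and nearly coincide after merging within 24 nt (20.8% and 20.5%).

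*QDPR*, an enzyme of tetrahydrobiopterin recycling that was among the oligodendrocyte markers, had 21 deposited sites in brain, 8 after merging within 24 nt. The 22 deposited sites of *MBP* there came down to 4. In H1, *SEPHS1*, a selenophosphate synthetase homologue, had the most deposited sites, 20, which merged to 4. *SRSF3*, a splicing factor, and *RPL13*, a ribosomal protein gene, each had 18 there, which merged to 5 each. *SET*, a histone chaperone, had 18 and *HNRNPC*, an RNA-binding protein, 17, which merged to 4 and 5. In brain *RPL13* had 21 sites and *KIAA0930* 19, which merged to 6 and 4.

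Most site positions were common to both samples. In the 8736 genes with an Ensembl ID in both, 69.5% of 10393 H1 sites had a brain site within 24 nt on the same strand (exact 95% interval 68.6 to 70.4), and 61.2% of 14456 brain sites had an H1 site that close (60.4 to 61.9). With every site displaced by 500 nt upstream, 0.587% and 0.422% met this distance.

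Within the same terminal exon, the mean long-read end lay further downstream in brain than in H1 in most genes compared. Of 1097 genes with at least 20 reads in each sample, 73.2% had a more distal mean end position in brain (exact 95% interval 70.5 to 75.8), and the median shift was 17.8 nt. That share counts any shift above 0 nt, also in genes with a single end. The median was 8.61 nt with at least 5 reads, 9.41 nt with at least 50 and 36.3 nt over all sites of a gene. It was 0 nt by the unweighted mean over distinct sites and by the most used site, which differed in 187 genes. In 881 genes the reads fell at 2 or more separate ends, and Fisher's exact test (two-sided, Benjamini-Hochberg adjusted) on the 2 most used ends found a higher distal share in brain in 230 genes and in H1 in 30. By the size of the molecules, 153 and 8 of these calls had their ends in different size fractions, 54 and 17 had both over 3 kb, and 23 and 5 had both in the same fraction of up to 3 kb.

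*TXNL1*, which encodes a thioredoxin-like protein, had the largest shift toward the distal end in brain. On chromosome 18, minus strand of build hg38, its proximal end lay at 56602826 and its distal end at 56597211. None of 90 H1 reads used the distal end (0%, upper limit of the exact interval 4.02%), against 411 of 423 brain reads (97.2%, 95.1 to 98.5, adjusted p = 8.8e-85 by Fisher's exact test). For *SC5D*, an enzyme of cholesterol synthesis, the distal share was 0% of 48 reads in H1 and 95.1% of 144 in brain. *AK4*, a mitochondrial adenylate kinase, had distal shares of 9.68% and 95.9%, and *ABLIM1*, an actin-binding protein, 23.1% and 98.6%. *EIF3F*, a subunit of translation initiation factor eIF3, went from 0% in H1 to 64.7% in brain, *SDHC*, a subunit of succinate dehydrogenase, from 0% to 58.6%, and *VAPA*, an endoplasmic reticulum membrane protein, from 0% to 56.1%. At these read numbers, a share of 0% in H1 allows up to 7.40% for *SC5D* and *VAPA*, 2.02% for *EIF3F* and 3.27% for *SDHC* (exact intervals). *NTPCR*, *SYNJ2BP* and *YIPF6* completed the 10 largest shifts, with distal shares in brain of 78.1%, 71.4% and 42.9%. In all 10 genes the distal ends belonged to molecules of 6366 to 7164 nt. For *TXNL1*, *SC5D* and *VAPA* the short reads placed 14, 10 and 23 counts at the proximal end in brain and 0 at the distal end. For *AK4* and *ABLIM1* they placed 0 at the proximal end and 22 and 85 at the distal end in brain. In H1 *AK4* had 0 proximal and 1 distal count and *ABLIM1* 0 at both ends, so no shift can be read from them. *SDHC* had 7 and 0 in H1 and 22 and 3 in brain, and *EIF3F* 20 and 0 in H1 and 3 and 1 in brain. *SYNJ2BP* had 0 and 3 in both samples. *NTPCR* had 5 and 0 in H1 and 0 and 1 in brain, and *YIPF6* 0 and 0 in H1 and 0 and 3 in brain.

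*ARPP19*, which encodes a phosphoprotein that inhibits protein phosphatase 2A, had a distal share of 76.6% in H1 (66.7 to 84.7) and 46.2% in brain (35.8 to 56.9, adjusted p = 1.6e-04 by Fisher's exact test). Its brain mean lay upstream of the H1 mean, by a difference of -1014 nt. *RPL13A*, a ribosomal protein gene on chromosome 19 with ends at 49491838 and 49492300, used the distal end in 74.2% of 621 H1 reads and 30.8% of 91 brain reads. *VPS41*, which acts in vesicle transport, had 84.6% and 21.7%, *EID1*, an inhibitor of differentiation, 97.3% and 54.6%, and *ADD3*, a membrane skeleton protein, 50.0% and 9.52%. For *RPL13A* nearly all short reads lay at the distal end in both samples, with 2 counts at the proximal and 101 at the distal end in H1 and 0 and 131 in brain. For *EID1* they ran against the long reads, with 12 and 19 counts in H1 and 0 and 34 in brain. For *ARPP19* they gave 3 and 12 in H1 and 10 and 59 in brain, for *ADD3* 0 and 33 in brain, and for *VPS41* 37 and 0 in brain. *PPP1R15B*, *TMBIM4*, *DNAJA1*, *PJA2* and *MTREX* completed this group, with distal shares in brain of 43.8%, 6.67%, 13.3%, 61.3% and 52.2% against 92.3%, 48.4%, 50.0%, 95.2% and 81.0% in H1.

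**Figure D3:**
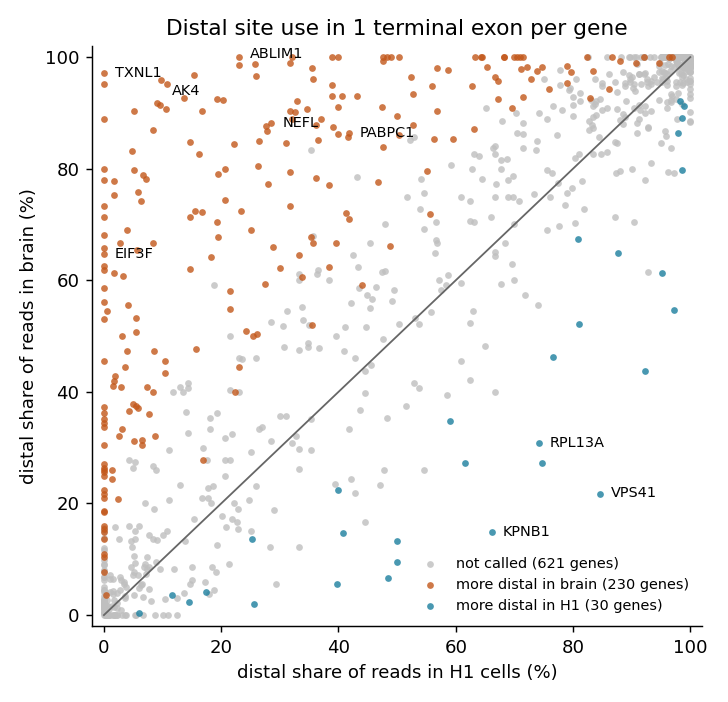
Distal share of long reads in H1 (x axis, %) and in brain (y axis, %) at the 2 most used ends of a terminal exon, 1 point per gene for 881 genes, with the diagonal drawn. The 230 genes called more distal in brain lie above the diagonal and the 30 called more distal in H1 below it.

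Of the cleavage and polyadenylation factors, 6 of 25 had enough reads, 5 of these had 2 ends to test, and 3 had a higher distal share in brain, also 3 adjusted over the list alone. These were *PABPC1*, the cytoplasmic poly(A)-binding protein, with 41.8% in H1 and 86.3% in brain, *CPSF6*, a subunit of cleavage factor I, with 16.2% and 82.6%, and *FIP1L1*, a subunit of the cleavage and polyadenylation specificity factor, with 0% of 11 reads (up to 28.5% allowed) and 62.5% of 24. For *CPSF6* and *FIP1L1* the ends belonged to molecules in different size fractions, of 2195 and 6612 nt and of 2184 and 6984 nt. Short reads there were too few, with 1 proximal and 0 distal counts in H1 for each gene. In brain they gave 0 and 2 for *CPSF6* and 1 and 0 for *FIP1L1*. Both ends of *PABPC1* belonged to molecules of over 3 kb, and its short reads gave 22 and 32 in H1 and 3 and 22 in brain. None of the 3 tested regulators of site choice passed over all genes (*TARDBP*, 21.5% and 40.3%, adjusted p = 0.081 by Fisher's exact test). Among 5 measured genes known for long 3' UTRs in brain, *KPNB1*, a nuclear import receptor, had a lower distal share in brain, 14.8% against 66.2%. Adjusted over the list alone, *TARDBP* and *CALM2* passed as well. The mean end of *KPNB1* was nevertheless more distal in brain, by 69.6 nt, since reads outside its 2 main ends count in the mean. *NEFL*, the neurofilament light chain, had a distal share of 28.6% in H1 and 88.2% in brain, and it was 1 of 2 neuron markers tested.

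Among 14 tested ribosomal protein genes, *RPL15* had a higher distal share in brain (71.9% against 55.6%), *RPL13A* a lower one, and 12 did not pass, while 8 others had a single end and were not tested. Of 13 tested housekeeping genes, 3 had a higher distal share in brain, or 2 adjusted over the list alone. For *EEF1A1* it was 0% of 5272 reads in H1 (up to 0.070% allowed) and 7.73% of 699 in brain, and for *HNRNPA1*, an RNA-binding protein, 48.7% and 66.1%. *YWHAZ*, a 14-3-3 protein, passed over all genes only, with 35.4% and 52.0%, and its mean end lay 3.88 nt further upstream in brain. At the ends of *EEF1A1* the short reads placed 744 proximal and 4 distal counts in H1 and 253 and 1 in brain, without such a shift. For *YWHAZ* they ran against the long reads, with 11 and 17 in H1 and 20 and 4 in brain. For *HNRNPA1* they gave 111 and 93 in H1 and 2 and 4 in brain. None of 5 tested myelin and cholesterol genes or 2 tested stress genes passed. The 3 synaptic and transport genes with enough reads had a single end each, so none was tested. Of 2 tested astrocyte markers *GLUL*, glutamine synthetase, passed with 0.392% in H1 and 3.56% in brain. The lists of pluripotency genes, oligodendrocyte markers and cell cycle genes had 1 tested gene each, which did not pass, and microglia, endothelial, blood and other-lineage markers had 0.

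In brain, some splice isoforms with the same terminal exon ended at different sites. For each gene the 2 isoforms with the most reads were compared at their 2 most used deposited sites, and 8 of 1003 genes passed Fisher's exact test after adjustment. *DDX5*, an RNA helicase, was one of them. Its 13-exon isoform used the distal of the sites at 64499620 and 64498254 on chromosome 17 in 38.5% of 361 reads (exact 95% interval 33.5 to 43.7), and a 12-exon isoform in 1.14% of 88 (0.029 to 6.17, adjusted p = 1.9e-12 by Fisher's exact test). *CLMN*, which encodes calmin, had 95.6% in a 13-exon and 21.1% in a 12-exon isoform. *CNP*, a myelin enzyme, had 9.33% in a 4-exon and 39.6% in a 2-exon isoform, and *CTNNA1*, alpha-catenin, 89.5% and 42.9% in 2 isoforms of 18 exons. The sites lay 1366 nt apart in *DDX5*, 3124 nt in *CLMN*, 2564 nt in *CNP* and 318 nt in *CTNNA1*. Molecule length was not held equal between the isoforms or the sites of a pair.

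In H1, 0 of 724 genes passed the same Fisher's exact test after adjustment, and 12 had an unadjusted p under 0.05, against 43 in brain. The smallest adjusted p in H1 was 0.16 by Fisher's exact test, and 0 genes also passed with at least 5 reads per isoform (10 of 268 unadjusted) and with ends merged (32 of 2981 unadjusted). The second isoform of an H1 pair had a median of 2 reads at the 2 sites, and that of a brain pair 3, so differences between most pairs were not detectable at this depth. Whether the samples differ in this respect was not tested.

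**Figure D4:**
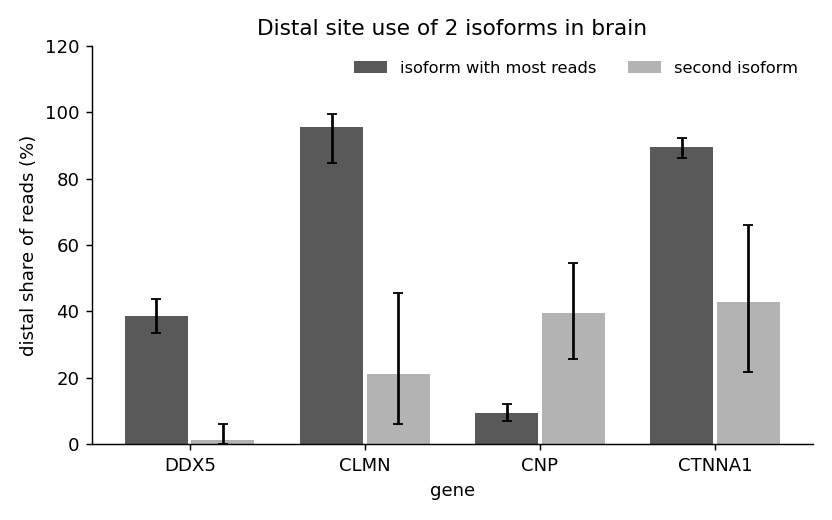
Distal share of long reads (y axis, %) in brain for the isoform with the most reads and the second isoform of 4 genes (x axis). Error bars are exact 95% binomial intervals, which cover counting error only. The share is higher in the second isoform of *CNP* and lower in that of *DDX5*, *CLMN* and *CTNNA1*.

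Gene levels were compared as long reads scaled to each library's total (RPM). Over the 8723 genes with reads in both samples, the median log2 ratio of brain over H1 was -1.19, so each list is also given relative to it. The random lists below were matched on mean level and not on transcript length. Long-read ratios differed by length, with a median of -2.49 at 1 to 2 kb and 2.79 over 6 kb. How far length sets the percentile of a list was not tested. The deposited rows were isoforms, and list members with 0 long reads in a sample also had 0 short-read counts there. For such genes the short reads are not a separate check. Genes named for going against their list were chosen after their values were seen. Of the 10 largest differences toward brain, 5 were of myelin, astrocyte or axon transport genes. *MBP* had 112868 reads in brain and 0 in H1, at least 16448-fold higher. *GFAP*, the astrocyte intermediate filament, had 9596 and 0, at least 1398-fold higher, each bound taking 3 reads as the floor of the library at 0. *MAG*, a myelin adhesion molecule, was at least 153-fold higher. *ERMN*, an oligodendrocyte cytoskeletal protein, had 4417 reads in brain and 1 in H1, a ratio of 1931 (exact 95% interval 346 to 76289). *KIF1A*, a kinesin motor of axonal transport, had 1731 and 1, a ratio of 757 (136 to 29908).

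*PTPN11*, a protein tyrosine phosphatase, *FGF1*, a fibroblast growth factor, *MTURN*, *PCGF5* and *NIPA1* completed the 10 largest differences toward brain. *PTPN11* had 13342 long reads in brain and 3 in H1, but 32 short-read counts at its sites in brain and 6 in H1. *PCGF5*, a Polycomb group protein, had 1309 and 0 long reads but 4 and 0 short-read counts. Toward H1, the 10 largest differences were all of genes with 0 reads in brain. *CLDN6*, a claudin of tight junctions, was at least 365-fold lower in brain, *POU5F1*, a core pluripotency transcription factor, at least 290-fold lower, and *CRIPTO*, a Nodal co-receptor, at least 290-fold lower. *SINHCAF*, *IGF2BP3*, *PMAIP1*, *DPPA4*, *KRT18*, *CTSV* and *MFAP2* followed, at least 160-fold to 278-fold lower.

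All 9 pluripotency genes with at least 50 reads in either sample lay below the all-gene median, and 6 of them had 0 reads in brain. Their median log2 ratio was -7.81, or -6.61 relative to all genes (percentile 0 among 10000 random lists matched on mean level), and -6.21 with genes at 0 set to their bound. *CD9*, a tetraspanin found in many cell types, lay nearest to it, with a log2 ratio of -1.74. All 15 cell cycle genes also lay below it, with a median of -6.08 (-4.88 relative to all genes, percentile 0, and -5.40 at the bounds). *CCNB1*, cyclin B1, was at least 155-fold lower in brain, *BIRC5*, survivin, at least 95.3-fold lower, and *MCM7*, a replicative helicase subunit, had a log2 ratio of -1.34, with 34 short-read counts in H1 and 103 in brain, or 0.25 above the all-gene median.

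All 12 oligodendrocyte markers lay above the all-gene median. Their median log2 ratio was 6.27, or 7.47 relative to all genes (percentile 100), and 5.23 with genes at 0 set to their bound. Of 10 astrocyte markers, 9 lay above the all-gene median and *GJA1*, a gap junction protein, below it, with a list median of 4.25 log2 (5.45 relative, percentile 99.4, and 3.45 at the bounds). The synaptic and axon transport list had 8 of 9 genes above and a median of 3.84 (5.04 relative, percentile 98.3, and 3.84 at the bounds). *KIF5A*, a neuronal kinesin, was at least 107-fold higher in brain, and *DCTN1*, a dynactin subunit, 8.87-fold higher. Of 7 neuron markers 5 lay above, and the list median of 0.69 (1.88 relative) was within the range of random lists (percentile 76.6). *UCHL1* and *VSNL1*, both neuronal proteins, were lower in brain, with log2 ratios of -4.08 and -4.29. The short reads gave the other direction for *VSNL1*, with 2 counts in H1 and 167 in brain, or 4.49 log2 above the all-gene median, and for *UCHL1* 42 and 74, or -0.52 relative to it. With short-read counts at sites instead, 12 of 13 measured neuron markers lay above the all-gene median (percentile 98.4). Of these 13, 8 had 0 short-read counts in H1. Genes without H1 long reads, such as *KIF5A*, also lack short-read counts there, so this is not a fully separate check. The random lists spanned 0.50 to 4.39 log2 against an all-gene median of -0.81, so a list median above the latter was usual.

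The Alzheimer's disease list had 6 of 7 genes above the all-gene median and a median log2 ratio of 4.84 (6.03 relative, percentile 99.8, and 4.58 at the bounds). No brain of a donor without the disease was included, so disease, tissue and donor cannot be told apart here. *APOE* and *CLU* of this list were also among the astrocyte markers. *APP*, the amyloid precursor, had 327 reads in brain and 3 in H1, *BIN1*, a membrane-shaping protein, 164 and 0, and *CLU*, clusterin, 855 and 317, while *ADAM10*, an alpha-secretase, had 46 and 118. Without the read minimum, 26 genes of this list were measured and their median was 0.11 (percentile 98.0). In short-read counts at sites the list had 5 measured genes and percentile 62.3. Of the genes known for long 3' UTRs in brain, 11 of 12 lay above (median 2.87, 4.07 relative, percentile 99.0, and 2.72 at the bounds), with random lists not matched on transcript length. In short-read counts all 14 measured lay above, but with percentile 29.5 among random lists. Those lists spanned 0.23 to 4.18 log2 against an all-gene median of -0.81, so a list median above the latter was usual. *NTRK2*, a neurotrophin receptor, was at least 40.4-fold higher in brain. The myelin and cholesterol list had 8 of 12 above (median 3.12, 4.32 relative, percentile 99.7, also 3.12 at the bounds), and *FDFT1*, an enzyme of cholesterol synthesis, had a log2 ratio of -3.32. In short-read counts *FDFT1* had 51 in H1 and 170 in brain, or 0.40 relative to all genes, and all 9 measured genes of this list lay above (percentile 97.96).

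In long reads, the machinery of 3' end formation lay within the range of random lists. Of 9 measured cleavage and polyadenylation factors 5 lay above the all-gene median and 4 below, and the list median was -0.91 scaled to the totals but 0.28 relative to all genes (percentile 59.6). *PPP1CA*, a phosphatase subunit, had 30 reads in brain and 279 in H1, and *PCF11*, a termination factor, 87 and 6. *PABPC1*, with 471 and 388, had a log2 ratio of -0.91 by totals and 0.28 relative to all genes. The short reads gave the other direction relative to all genes for *PPP1CA*, with 19 counts in H1 and 63 in brain (0.36), and for *PABPC1*, with 76 and 25 (-2.89), and were too few for *PCF11*, with 1 and 0. Regulators of site choice also split 5 and 4, with a median of -1.12 by totals and 0.07 relative to all genes (percentile 30.4). *SRSF3* and *SRSF7*, splicing factors, were lower in brain with log2 ratios of -5.43 and -5.79. *ELAVL3*, a neuronal RNA-binding protein, was at least 14.7-fold higher, and *HNRNPC* had a log2 ratio of -3.66. In short-read counts both lists lay outside the range of their random lists, but those ranges lay mostly toward brain. They were -0.0059 to 4.58 log2 for the cleavage and polyadenylation factors and -0.59 to 4.16 for the regulators. The all-gene median was -0.81. A low percentile there can therefore go with a list median above that of all genes. The 8 measured regulators, 4 of them with 0 counts in H1, had a median of 4.20 (percentile 98.2). The 4 measured cleavage and polyadenylation factors had one of -0.13, or 0.68 relative to all genes (percentile 1.52), with 3 above the all-gene median.

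Ribosomal protein genes, whose transcripts are short, had 26 of 28 members below the all-gene median and a list median of -3.25 (-2.06 relative, percentile 6.38). *RPLP0* had 118 reads in brain and 2268 in H1. Housekeeping genes had 16 of 19 below (median -3.71, -2.52 relative, percentile 4.1), among them *PGK1*, a glycolytic enzyme, with 8 and 326 reads. Both percentiles lay within the middle 95% of random lists, but without the read minimum they were 0.96 over 37 ribosomal protein genes and 1.67 over 21 housekeeping genes, below it. In short-read counts at sites the corresponding medians relative to all genes were -0.73 and -0.41. Of 6 stress genes, 3 lay above and 3 below (median -0.10 by totals, 1.10 relative to all genes, percentile 75.5). Without the read minimum 8 of 11 lay above, at percentile 99.88. Among the 6 genes at the read minimum, the highest were *HSP90AA1*, a chaperone, with 367 reads in brain and 7 in H1, and *HSPA1A*, an inducible heat shock protein, with 138 and 5. In short-read counts *HSP90AA1* had 253 in brain and 88 in H1, 0.19 log2 above the all-gene median, and *HSPA1A* 3 and 0. Microglia markers were too low for a median at the read minimum, with 106 reads over 9 genes in brain and 40 over 2 genes in H1, and without the minimum their median was 1.61 (percentile 99.1). Endothelial and pericyte markers had 83 and 54 reads, blood markers 14 and 0, and markers of other lineages 6 and 1.

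**Figure D5:**
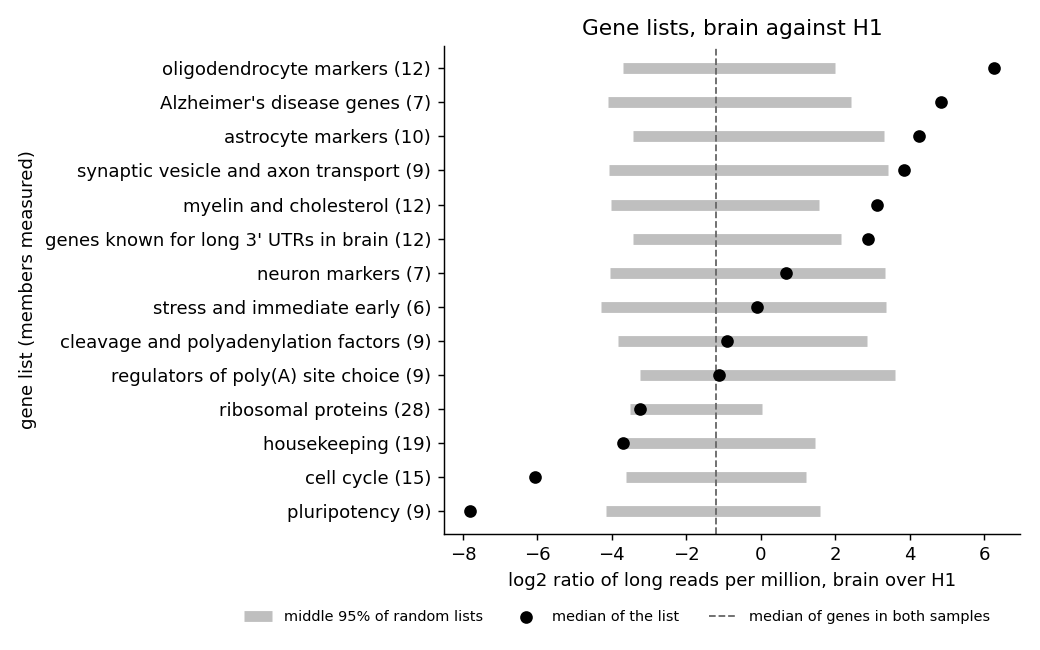
Median log2 ratio of long reads (RPM), brain over H1 (x axis), for 14 gene lists (y axis, members measured in brackets). Grey bars span the middle 95% of 10000 random lists matched on mean level, and the dashed line is the all-gene median of -1.19. Oligodendrocyte markers (6.27) lie furthest above the random range, and pluripotency genes (-7.81) furthest below it.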

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

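The tests of merging, of thinning the long reads, of short reads at sites in different size fractions, of the gap between long and short reads by length, and of lengths by H1 isoforms were chosen after the result was seen. Some deposited data lie outside the comparisons above. The short reads placed 3157 sites in H1 and 6204 in brain where no long read of the isoform ended within 10 nt. Single-exon loci without a gene ID held 3296 long reads in H1 and 10032 in brain. Mitochondrial genes held 4143 long reads in H1 and 141433 in brain. No control sample was at hand for these values.

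The larger share of genes with several deposited sites in brain was 11.2 points. After merging sites within 24 nt the difference was -0.38 points, so closely spaced end positions may account for it. More long reads per gene argue poorly for it, since with equal long reads in shared genes the difference was 12.03 points. With both long reads and short-read counts made equal in 3576 genes, the difference was -5.12 points (46.4% in brain and 51.5% in H1), which is consistent with deeper short reads listing more neighbouring positions. That value removes the difference and turns it round, and the limit it was read against was widened to negative values after it was seen; a difference between brain and stem cells stays open, as untested.

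The excess of distal ends in brain may reflect the weight of long size fractions in the brain long-read library. Where both ends belonged to molecules of the same fraction of up to 3 kb, 23 of 28 calls were distal in brain, or 82.1% (exact 95% interval 63.1 to 93.9). By computed lengths, this argues against the weights of the fractions alone as the cause of these calls. Neither how sharply the fractions were separated nor a length effect within a fraction was tested, so size selection is not excluded for these genes. In this group the short reads gave a higher distal share in brain in 58.2% of 79 genes with a difference (46.6 to 69.2), which reaches 50%. For ends in different fractions, 190 genes had enough short-read counts, with a median difference in distal share of 0 points against 7.89 points in long reads. Of the 117 genes with a difference, the short reads gave a higher distal share in brain in 63.2% (53.8 to 72.0). This lies above 50% and by the limit first written would argue against the fractions. That reading was changed after the values were seen, because short reads also pointed to brain in 81.25% of 16 genes called more distal in H1 (54.4 to 95.95), and in 77.5% of 71 called more distal in brain (66.0 to 86.5), so their direction did not follow the calls. For these genes size fractions and a difference between brain and stem cells cannot be told apart, since the short reads do not discriminate, and the latter stays open, as untested, for both groups.

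Transcripts of over 3 kb were higher in brain in the long reads than those of 1 to 2 kb, most of all above 6 kb. Over 3450 genes, the median log2 ratio was -2.49 for transcripts of 1 to 2 kb, 0.20 for those of 3 to 6 kb and 2.79 for those of over 6 kb, against -0.33, 0.32 and 1.45 in short-read counts at sites. The gap between the kinds of read was larger by 2.47 over 3 kb than at 1 to 2 kb (bootstrap 95% interval 2.25 to 2.69). These lengths came from reads of both samples, so brain reads could set the class of a gene. By the length of the H1 isoform with most reads, the gap was larger by 1.59 at 3 to 6 kb than at 1 to 2 kb (1.37 to 1.83), consistent with a library effect of the size fractions for this part. It was larger by a further 1.52 over 6 kb than at 3 to 6 kb (0.81 to 1.93). This argues against the weights of the fractions as the whole cause, since all these lengths belong to the fraction of over 3 kb, and the first reading of the 2.47 was changed for this reason. The short-read ratio differed by -0.14 between these 2 lengths (-0.51 to 0.38). This argues against more brain RNA from genes with H1 isoforms of over 6 kb as the source of this further step. A difference within the fraction of over 3 kb was not tested. By lengths from both samples, the short reads differed between over 3 kb and 1 to 2 kb by 0.95 (0.71 to 1.21). That interval spans the limit of 1 set before it was computed. By H1 isoforms, in 3068 genes with H1 reads, the difference was 0.10 (-0.14 to 0.32), under that limit. This argues against more brain RNA from genes with long H1 isoforms as the cause in these genes. Longer isoforms of the same genes in brain would not change these values and were not tested. A larger part of long transcripts also stays open for genes with 0 long reads in H1.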

How the results depend on the processing

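Of 107 alternative values, 76 stayed within the set limits, 31 moved, and no list median outside the random range in the main setting changed sign. With at least 5 long reads per site, 7407 H1 and 15500 brain sites remained. With at least 5 reads per isoform (chosen after seeing the data), 6486 H1 and 9978 brain isoforms remained. The share of genes with several sites was 20.8% in H1 and 20.5% in brain after merging within 24 nt, 18.3% in both within 100 nt, 48.5% and 60.2% without sites under 5% of reads, and 53.8% and 65.9% after thinning. Sites of H1 near a brain site were 67.4% within 10 nt and 71.2% within 100 nt, and brain sites near an H1 site 59.1% and 62.5%. Genes more distal in brain numbered 364 with at least 5 reads, when 68.8% of genes had a more distal mean in brain, and 81 with at least 50, when 19 were more distal in H1. By the most used site, 92.0% of the 187 genes that differed were more distal in brain. Within the same size fraction of up to 3 kb (chosen after seeing the data), 23 genes were more distal in brain and 5 in H1, with fewer genes tested. Isoform pairs called in brain rose to 22 with ends merged, over 3678 genes, and H1 gave 0 under each setting. The pluripotency median was -11.12 with 0.1 read added and -4.78 without the filter on low genes. Without that filter the Alzheimer's disease median was 0.11, the neuron median changed sign to -0.19 inside the random range, and the stress median changed sign to 3.27, outside that range (percentile 99.88), over more genes. In short-read counts (chosen after seeing the data), the median for regulators of site choice changed sign to 4.20, outside the random range (percentile 98.2), and was -1.54 for ribosomal proteins and -1.22 for housekeeping genes. The cause of each of these differences was not tested, except where fewer or more genes entered. Scaling to the median ratio sets the all-gene median of -1.19 to 0, which changed the sign of 3 list medians inside the random range (cleavage factors, regulators of site choice and stress genes). No paired analysis was possible because each group has 1 sample. Poly(A) signals with both sets of motifs were not run, since they need a genome sequence. Depth limits genes with few reads. At the depth of these libraries the test called 20% of simulated changes of 20 points, centred on equal use of both ends.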

Other observations

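The following comparison and the choice of its genes were made after seeing the data. Several genes used another last exon in brain than in H1. The 2 most used terminal exons, told apart by their splice acceptors, were compared in 487 genes with at least 20 reads in each sample over all their terminal exons. Fisher's exact test (two-sided, Benjamini-Hochberg adjusted) called 21 genes with more use of the downstream exon in brain and 17 with more use of the upstream exon, and in 16 of these the more used of the 2 exons changed.

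*EIF4E2*, a cap-binding protein, used the downstream exon in 11.1% of reads in H1 (exact 95% interval 5.46 to 19.5) and 95.3% in brain (84.2 to 99.4). On chromosome 2 of hg38 these exons begin at 232568945 and 232580904. *RBMX*, an RNA-binding protein of the hnRNP family, had 18.8% of 239 reads in H1 and 91.2% of 205 in brain, and *MYH10*, non-muscle myosin IIB, 47.4% and 95.8%. In the other direction, *ENSA*, an inhibitor of protein phosphatase 2A, had 83.0% in H1 and 4.43% in brain. *NAP1L1*, a histone chaperone, had 70.3% and 10.8%, and *SEPTIN11*, a septin, 93.4% and 26.7%. *GPM6B*, a membrane glycoprotein of neurons and oligodendrocytes, had 52.8% of 53 reads and 0.299% of 668. Molecule length was not held equal in this comparison.

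Of the immediate early genes, *JUN* and *JUNB*, AP-1 transcription factors, had 23 and 28 long reads in brain and 0 in H1, at least 3.35-fold and 4.08-fold higher, and *FOS*, their partner, had 43 and 13, a ratio of 1.45 (0.763 to 2.93).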
